A study of Homo sapiens with 6 samples.

How the data were processed

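Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in NCI-H146, an established human small cell lung cancer (SCLC) cell line. Cells received DMSO vehicle or valemetostat, a dual EZH1 and EZH2 inhibitor, at 2.5 µM, and were collected on day 9. Each group had 3 libraries, which the series design calls biological replicates. Per the labels' protocols, 50000 nuclei per sample went into a commercial ATAC-seq kit, and both ends of each fragment were read over 100 bp on a NovaSeq 6000.

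Per the submitters' processing notes, the tools were Trim Galore, Bowtie2, Picard, SAMtools, MACS2 and bedtools and the genome build was hg38, with no versions given. The settings of each step, including any shift of reads for transposase insertion, duplicate removal or blacklist filter, are not given in the sources used here. The authors deposited 1 MACS2 narrowPeak list per library, so peaks were called per sample. In each deposited list, a peak has an integer score, a fold enrichment at its summit over the background, a −log10 p-value and a −log10 q-value. These are the authors' values for that peak, and they were used to describe, rank or filter peaks within a list. The lowest −log10 q over the lists was 1.30, which is a q of 0.05. No list held the same interval more than once.

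Read counts were not used here, and total sequencing depth is unknown. Where a MACS2 peak lies on the genome-wide background, its fold is a whole pileup plus 1 over the background plus 1, so the step of the fold values gives the background pileup. Between 21.1% and 28.7% of peaks lay on this grid within 0.001. The background pileup per 1000 bp of the shortest peak width, a stand-in for fragment size, is called the depth index below. It is a relative estimate with no error of its own, used to describe the libraries and to weigh depth as an explanation.

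Chromosomes 1 to 22 and X were analysed. Regions were the union of all peaks of the 6 lists, merged where peaks overlapped by 1 bp or more. A region was present in a library with 1 bp or more of a called peak. Gained regions were called in 3 of 3 valemetostat and 0 of 3 vehicle libraries, and lost regions the reverse. These counts were set against the 9 other splits of the 6 libraries into groups of 3. Values per library were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1. Shares of regions were compared by two-sided Fisher exact tests with 95% Wilson intervals. Regions are not independent units, so these describe the region sets. Fisher p-values, the intervals and shuffles cover these lists and not the variation between cultures.

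The annotation was the RefSeq gene table of GRCh38.p14, which shares coordinates with hg38. It gives gene starts and ends without strand, exons or sequence, and no genome sequence was used here. The transcription start was therefore unknown, and the planned window around it was replaced by windows of 10 kb either side of both annotated ends of each gene. A region counted as near a gene end within 1 kb of either end. Position in exons, introns or UTRs was not analysed here, nor were motifs, GC or CpG content, all of which need a sequence or exon model.

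For each of 19974 protein-coding genes, the peak-covered length in these windows was scaled to the mean total covered length of the libraries. Genes covered in at least 3 of 6 libraries were tested with limma 3.58.1 in R 4.3.3 (trend and robust empirical Bayes) on log2(bp + 500), with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 change is thus one of called sequence on that scale, not of reads, and it understates changes of genes with little coverage. Gene lists were fixed before the data were examined and tested with limma's camera at an inter-gene correlation of 0.01, with the estimated correlation beside it. Camera compares a list with all other genes. The mean log2 change of each list was also placed among 10000 random lists of the same size matched on mean peak-covered length, as a description of these libraries. Of 895 listed symbols, 894 were in the annotation. On simulated values for 18494 genes, the gene test recovered 75% of changes of 1.0 and 23% of changes of 0.5 on the log2 scale, and called 0 unchanged genes. Only 200 genes were changed, and residuals were shuffled separately for each gene. The simulation thus holds no effect shared by all genes of a library, and it does not give the rate of false calls from such effects. On simulated peak lists, the counting rule found all 486 gained and 302 lost patterns, some of which arose by chance among randomly called regions. Planted regions had no missed calls, so this checks the counting and not its error rate.

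Named genes followed a rule with 4 parts. They were the 10 called genes with the largest change in each direction whose groups did not overlap, and up to 4 called members of each list. The 5 genes with the most gained and the 5 with the most lost regions followed, and a fixed set that held EZH2, EZH1, NEUROD1, HLA-B, HLA-C, B2M, TAP1, NLRC5, SLFN11, CDKN2A and CDKN1A. Some genes that met the rule are not reported here. Alternatives covered stricter −log10 q, equal list lengths, other overlap rules, window sizes, pseudocounts, scaling and filters. Each library was also left out in turn, and the replicate number was used as a block. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.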

Results

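The series holds 6 ATAC-seq peak lists from NCI-H146 cells, a neuroendocrine SCLC line, after 9 days with valemetostat (3 libraries) or DMSO vehicle (3 libraries). EZH2 and EZH1 are the catalytic subunits of PRC2, which methylates histone H3 at lysine 27 and keeps developmental genes silent. The series title places the experiment in the question of how EZH2 inhibition changes chromatin architecture and immune recognition in SCLC. The lists held 106211, 104635 and 102277 peaks in vehicle replicates 1, 2 and 3, and 115309, 111524 and 107483 in valemetostat replicates 1, 2 and 3. The depth index was 12.5, 10.6 and 10.8 in vehicle and 11.9, 9.11 and 8.89 in valemetostat libraries, so 2 treated libraries were below every vehicle library.

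The first comparison asked how much of the accessible landscape differed between treatments. Of 160204 regions, 68962 were called in all 6 libraries, 9016 were gained with valemetostat and 4040 were lost. The genes with the most gained regions near their ends included LOC124901165 (6 gained regions), SIRPA (6), SLCO4A1 (6) and CCR6 (5, first by symbol among equals, with TWIST2 also at 5). SIRPA is an inhibitory receptor of myeloid cells, SLCO4A1 an organic anion transporter, CCR6 a chemokine receptor and TWIST2 a mesenchymal transcription factor. Lost regions were most frequent near C12orf56 (3 lost regions) and WHRN (3), followed by ADGRF3, AKNA and ANKH (2 each, first by symbol among equals). The 9 other splits of the 6 libraries gave between 142 and 517 such regions in a direction.

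**Figure D1:**
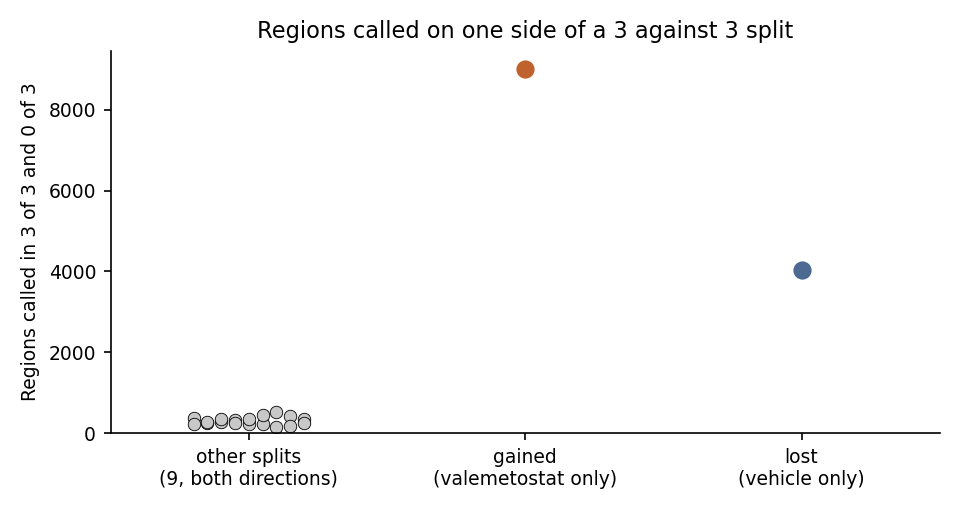
Number of regions (y axis) called in all 3 libraries on one side of a split and in 0 of 3 on the other, for the 9 other splits in both directions (grey) and for the real groups. The real groups gave 9016 gained and 4040 lost regions, against at most 517 in another split.

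Peak lists of the same treatment shared more sequence than lists of different treatments. The base-pair Jaccard index was 0.678 to 0.722 in the 6 same-group pairs and 0.586 to 0.608 in the 9 pairs between groups (difference 0.101, exact permutation p = 0.1 over 10 splits, the smallest possible). Valemetostat libraries had more peaks than vehicle libraries (111439 ± 3914 against 104374 ± 1980, SD, n = 3, exact permutation p = 0.1), and each was above every vehicle library. Their median peak width was smaller (479 ± 5.51 bp against 522 ± 39.8 bp, SD, n = 3, exact permutation p = 0.1), a difference of −43.3 bp that was −20.3 bp without vehicle replicate 1. It was −27.3 bp at −log10 q of 5 or more (exact permutation p = 0.3) and −11.3 bp at 10 or more (p = 0.9). Total covered length did not differ beyond the spread (62.9 ± 1.71 Mb against 63.7 ± 5.32 Mb, SD, n = 3, exact permutation p = 1.0), with a difference of −3.02 Mb at −log10 q of 5 or more (exact permutation p = 0.6) and −5.84 Mb at 10 or more (p = 0.1). Within the 63391 regions with 1 peak in each list, the median width was 602 ± 6.03 bp with valemetostat and 651 ± 44.7 bp in vehicle (SD, n = 3, exact permutation p = 0.1), a difference of −49.7 bp that was −23.8 bp without vehicle replicate 1. Vehicle replicate 1 stood apart, with a median width of 568 bp and 69.9 Mb covered. The excess of peaks was 139 at −log10 q of 5 or more (exact permutation p = 1.0) and turned at 10 or more, where the difference in mean peaks was −6217 (exact permutation p = 0.2), and gained and lost regions then numbered 4093 and 5028.

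**Figure D2:**
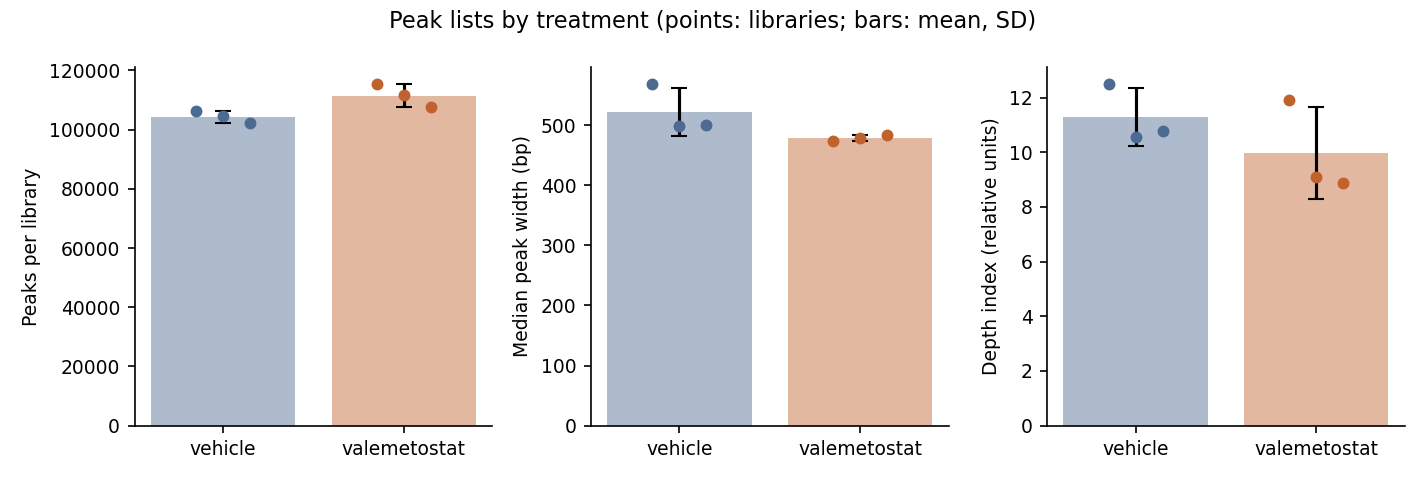
Peaks per library, median peak width in bp and depth index in relative units (y axes) for vehicle and valemetostat libraries; points are libraries and bars the group mean with SD. The 3 valemetostat libraries have more and narrower peaks than the 3 vehicle libraries, and 2 of them have the lowest depth index.

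Gained and lost regions both lay near gene ends less often than regions called in all 6 libraries. Of gained regions, 5.12% (95% Wilson interval 4.69 to 5.60%) were within 1 kb of an end of a protein-coding gene, of lost regions 5.17% (4.53 to 5.90%) and of regions called in all 6 libraries 21.2% (20.9 to 21.5%). The odds ratio against regions called in all libraries was 0.201 for gained and 0.203 for lost regions (Fisher exact p = 1.1e-174 for lost regions, smaller for gained). Gained and lost regions did not differ in this share (odds ratio 0.99, Fisher exact p = 0.898). Outside genes and beyond 1 kb of their ends lay 57.9% of gained, 45.2% of lost and 41.7% of regions called in all libraries. Regions called in all libraries were wider (median 828 bp, against 557 bp for gained and 451 bp for lost). Median −log10 q of gained peaks was 7.42 to 8.38 in valemetostat lists, against 25.8 to 32.5 for peaks called in all libraries. For lost peaks it was 8.18 to 10.9 in vehicle lists, against 37.6 to 49.9. These shares were not compared at equal width or strength. Gained regions were close together along chromosomes, with 1893 adjacent pairs against a mean of 525 and a highest value of 596 in 1000 shuffles within chromosomes. Lost regions had 171 pairs (shuffled mean 104, highest 139) and regions called in all libraries 34530 (29757, 30074), ratios to the shuffled mean of 1.64 and 1.16 against 3.61 for gained regions. The more common a kind of region, the lower the largest ratio it can reach. The value for regions called in all libraries is thus not on the scale of the others. The 144 windows of 1 Mb with the most gained regions, 5% of those with any region, held 34.9% of gained, 3.79% of lost, 7.05% of regions called in all libraries and 11.3% of all regions. They were chosen on gained regions, which in itself raises the gained share. Shuffling gave 17.8% on average and 18.5% at most for gained regions in windows chosen the same way. The window with the most gained regions was on chromosome 10 (131000001 to 132000000, 45 gained and 1 lost), which holds TCERG1L, PPP2R2D and BNIP3. A window on chromosome 7 (155000001 to 156000000) with EN2 and SHH had 40 gained and 1 lost, and one on chromosome 20 (59000001 to 60000000) with EDN3 had 36 gained and 0 lost.

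The second comparison asked which genes gained or lost called sequence near their ends. Many of the genes with the largest gains had 0 bp of called sequence in vehicle. A gene at 0 bp throughout a group shows no spread there. Its p-value rests on the other group and on pooling across genes, and does not measure variation between cultures of that group. TBX5, a heart and limb transcription factor (chromosome 12, 114353911 to 114408442), was covered by 2849.8 ± 159.9 bp of peaks with valemetostat and was at 0 bp in all 3 vehicle libraries (SD, n = 3, limma adjusted p = 9.56e-06). OLIG2, a glial and motor neuron factor (chromosome 21, 33025935 to 33029185), was at 2655 ± 245 bp against 0 bp, EDN3, an endothelin (chromosome 20, 59300611 to 59325992), at 2652 ± 555 bp against 0 bp, and SLC2A5, a fructose transporter (chromosome 1, 9035106 to 9094195), at 2805 ± 564 bp against 0 bp. MEDAG, an adipogenesis gene (2689 ± 232 bp), and TMEM238L (2971 ± 686 bp) were also at 0 bp in vehicle, and TWIST2 rose from 254 ± 80.7 to 4085 ± 474 bp (log2 change 2.60, SE 0.111, adjusted p = 2.77e-05). The neighbouring X-linked genes TEX28, OPN1MW2 and OPN1MW were at 3159 ± 703, 3032 ± 251 and 2965 ± 204 bp against 0 bp, but they lie in near-identical repeats whose reads map to several places, so they are uncertain.

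Of 18494 genes tested, 1742 were called higher and 2432 lower. More genes were higher than lower without vehicle replicate 2 (1395 against 1221), without vehicle replicate 3 (1419 against 1172) and in windows of 2 kb (706 against 589), and 1480 were lower without vehicle replicate 1 and 1463 without valemetostat replicate 2. The median log2 change was 0.83 among those called higher and −0.37 among those called lower, and it was −0.10 over all genes. A change above 1 was found in 678 genes called higher, and one below −1 in 33 called lower. A gained region lay near 68.1% of the genes called higher, and a lost region near 31.9% of those called lower, against 2.98% and 3.81% of genes not called. The gene value includes these regions, so the shares are not an independent test. The most reduced genes included AEBP2, an accessory subunit of PRC2 (chromosome 12, 19404072 to 19522227), at 136 ± 236 bp against 1484 ± 351 bp (log2 change −1.69, SE 0.253, adjusted p = 0.00354). LSMEM1 and RHOBTB3 were at 0 bp in all valemetostat libraries, against 761 ± 88.4 and 719.5 ± 82.6 bp in vehicle. GPHB5, a glycoprotein hormone subunit (log2 change −1.30), C7orf78 (−1.50), BAAT, a bile acid conjugating enzyme (−1.31), PKD2, a calcium channel of the primary cilium (−1.25), RAPSN (−1.20), KMO, an enzyme of tryptophan breakdown (−1.20), and LYG2 (−1.18) also fell. Centring each library on its median gene, a choice made after seeing the data, gave 1895 higher and 1010 lower (65.2% higher, against 41.7% without centring). With each region at one fixed width, also chosen after seeing the data, 1004 and 1060 genes were called, and AEBP2, C7orf78, BAAT, PKD2, KMO and LYG2 no longer passed.

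**Figure D3:**
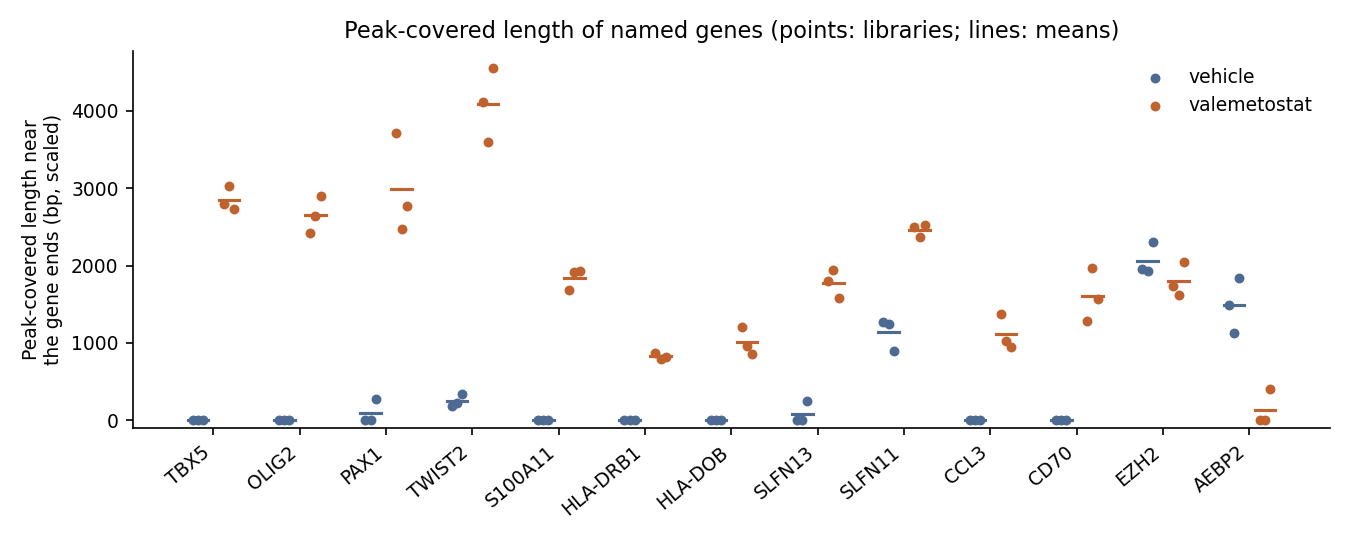
Peak-covered length near the gene ends (bp, scaled to the mean total covered length, y axis) for 13 named genes; points are libraries and lines group means. TBX5, OLIG2, S100A11, HLA-DRB1, HLA-DOB, CCL3 and CD70 are at 0 bp in all 3 vehicle libraries.

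Among developmental transcription factors often bound by PRC2, 32 of 102 tested genes rose, 14 fell and 56 did not pass (39 higher and 15 lower adjusted over the list alone). Members that rose included PAX1, a vertebral column factor (2983 ± 642 bp against 92.5 ± 160.2 bp, log2 change 2.57, SE 0.200, adjusted p = 0.000199), and IRX2, an Iroquois homeobox gene (1482 ± 480.2 bp against 0 bp, adjusted p = 0.000556), beside TBX5 and OLIG2. The list was called (camera adjusted p = 3.66e-06, and adjusted p = 0.0427 with an estimated correlation). Of 39 HOX cluster genes, 10 rose and 4 fell (the same numbers adjusted over the list alone), and the list was not called (adjusted p = 0.176). HOXC12 (log2 change 2.16, SE 0.212), HOXC13 (2.04, SE 0.134), HOXC11 (1.76, SE 0.0960) and HOXC5 (1.34, SE 0.140) rose, and the windows of HOXC13 and HOXC11 on chromosome 12 each overlap that of HOXC12. The HOX median was −0.07 while its mean was 0.21. In all genes tested, 9.42% were called higher and 13.2% lower.

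All 6 Schlafen genes, a family of interferon-responsive growth regulators on chromosome 17, rose (6 of 6 adjusted over the list alone; camera adjusted p = 1.87e-07, and adjusted p = 0.0453 with an estimated correlation). SLFN11, which sensitises cells to DNA-damaging drugs (35350305 to 35373621), was at 2464 ± 80.8 bp with valemetostat and 1139 ± 208 bp in vehicle (log2 change 0.86, SE 0.103, adjusted p = 0.0013). SLFN13 rose from 85.1 ± 147 to 1776 ± 184 bp (log2 change 1.98) and SLFN5 from 1240.4 ± 100.3 to 2239 ± 93.1 bp (0.66), and SLFN12 was at 947 ± 124 bp against 0 bp. Across the cluster, from 35223072 to 35580819, vehicle libraries had 7, 6 and 9 peaks and valemetostat libraries 21, 25 and 22. A region at the higher end of SLFN11 (35373437 to 35374895) and one at the lower end of SLFN5 (35242127 to 35243635) were called in all 6 libraries. The gained region in the windows of each gene lay beyond its other end (35345613 to 35346991 and 35278503 to 35279392). The genes are neighbours and related in sequence, so they are not independent members, and the calls of SLFN11 and SLFN5 ended in windows of 2 kb.

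**Figure D4:**
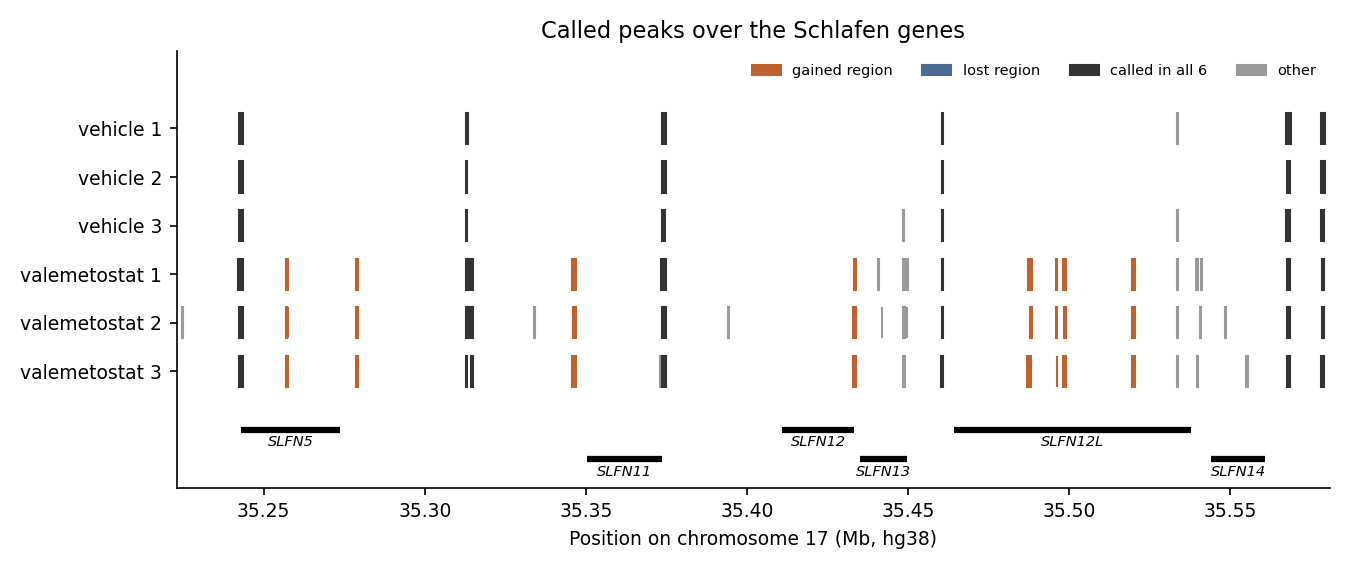
Called peaks in each of the 6 libraries (y axis) along chromosome 17 (x axis, Mb, hg38) over the 6 Schlafen genes (black lines), coloured by whether the region was gained, lost, called in all 6 libraries or other. Vehicle libraries have 7, 6 and 9 peaks here and valemetostat libraries 21, 25 and 22.

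Antigen presentation genes of MHC class II rose in 7 of 16 tested members and fell in 0 (8 higher adjusted over the list alone). HLA-DRB1 (832 ± 40.1 bp) and HLA-DQB1 (601 ± 254 bp), which encode antigen-presenting chains, were at 0 bp in vehicle, as was HLA-DOB (1008 ± 179 bp), and HLA-DOA rose from 353 ± 107 to 1793 ± 329.8 bp (log2 change 1.42, SE 0.138, adjusted p = 0.000547). The list was called (camera adjusted p = 3.12e-05), with an adjusted p = 0.0510 with an estimated correlation. In MHC class I presentation, 6 of 24 members rose and 4 fell (6 and 7 adjusted over the list alone), and the list was not called (adjusted p = 0.438). TAP2, a subunit of the peptide transporter, rose from 1608 ± 45.6 to 3642 ± 203 bp (log2 change 0.97, SE 0.0653, adjusted p = 9.12e-05), and PSMB9 (0.53), HLA-E (0.52), HLA-B (0.47) and TAP1 (0.32) rose less. The windows of HLA-DOB, TAP1 and PSMB9 each overlap that of TAP2, so the rises of these genes are not independent. ERAP2, a peptide-trimming enzyme, fell (log2 change −0.52). HLA-C (log2 change −0.04, adjusted p = 0.768), B2M (−0.25, 0.167) and NLRC5, the class I transactivator (−0.23, 0.260), did not pass. HLA genes are highly similar and polymorphic, so the placement of their reads is uncertain, and PSMB9, HLA-E and HLA-B did not pass in windows of 2 kb. With each region at one fixed width, TAP1 turned to −0.0449 (adjusted p = 0.157).

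Chemokines and cytokines rose in 9 of 44 tested members and fell in 5 (10 and 5 adjusted over the list alone; camera adjusted p = 0.0028, and adjusted p = 0.0663 with an estimated correlation). The call of this list ended without valemetostat replicate 1 (camera adjusted p = 0.0522). CCL3 (1118 ± 228 bp), CCL4 (699 ± 199.9 bp) and CXCL5 (433 ± 78.4 bp), which attract leukocytes, were at 0 bp in vehicle, and IL10 rose (log2 change 1.65, SE 0.242, adjusted p = 0.0033). The windows of CCL3 and CCL4 overlap. Ligands read by NK and T cells moved both ways, with 7 of 39 higher and 8 lower (8 and 8 adjusted over the list alone; camera adjusted p = 0.438). CD70, a co-stimulatory ligand, was at 1605 ± 343 bp against 0 bp, and CLEC2B (log2 change 1.51), CD48 (1.37) and MICA, a stress ligand of NK cells (1.10), rose. Interferon-stimulated genes were higher in 6 and lower in 10 of 59 members (the same adjusted over the list alone; camera adjusted p = 0.754). XAF1 (log2 change 1.29) and RTP4 (1.03, but −0.0540 with each region at one fixed width) rose, GBP4 was at 535 ± 261 bp against 0 bp, and SAMD9L fell (−1.17, adjusted p = 0.0479). Markers of blood cells, an unrelated lineage, rose as well in 10 of 39 members and fell in 1 (the same adjusted over the list alone; camera adjusted p = 0.00969, and adjusted p = 0.238 with an estimated correlation). ITGAM (log2 change 1.58) and ITGAX (1.58), myeloid integrins, rose, CD33 was at 985 ± 337 bp against 0 bp, and PRF1, perforin, was at 0 bp with valemetostat against 454 ± 42.5 bp.

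Non-neuroendocrine, Notch, YAP and mesenchymal genes rose in 13 of 70 tested members and fell in 4 (the same adjusted over the list alone; camera adjusted p = 0.00161, and adjusted p = 0.0510 with an estimated correlation). S100A11, a calcium-binding protein, was at 1840.0 ± 141 bp against 0 bp, and COL6A1, a collagen (log2 change 1.35, SE 0.193), and YAP1, the transcriptional effector of the Hippo pathway (1.15, SE 0.133, adjusted p = 0.00116), rose beside TWIST2. Neuroendocrine identity genes were higher in 4 and lower in 10 of 63 members (4 and 12 adjusted over the list alone; camera adjusted p = 0.176). NEUROD2 rose (log2 change 0.70, but −0.0105 in windows of 50 kb) and NEUROD4 (0.77) too, while ST18 fell (−0.89) and ELAVL4 was at 0 bp against 391 ± 229.8 bp. The lineage factor NEUROD1 (2849 ± 334 against 3178 ± 118 bp, log2 change −0.14, adjusted p = 0.240) did not pass.

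Of the PRC2 subunits and demethylases, 0 of 16 rose and 2 fell, AEBP2 and PHF19 (log2 change −0.74, adjusted p = 0.00641), and the list was not called (adjusted p = 0.256). PHF19 was at 0.30 in windows of 2 kb (adjusted p = 0.418), and neither passed with each region at one fixed width. EZH2, the drug's target, was at 1799 ± 224 bp against 2063 ± 209 bp (log2 change −0.16, SE 0.0963, adjusted p = 0.265) and EZH1 at −0.06 (adjusted p = 0.724). CDKN2A, a cell cycle inhibitor under PRC2 control in many cells, fell from 4601 ± 295 to 3626 ± 68.4 bp (log2 change −0.30, adjusted p = 0.01), and CDKN1A did not pass (−0.15, adjusted p = 0.295). The windows of CDKN2A held 0 lost regions and 2 regions called in all 6 libraries. The median log2 change was −0.10 over all genes and −0.16 for housekeeping genes, a control. Camera called 6 of 22 lists, all higher, and 2 with an estimated correlation, which were the PRC2-bound developmental factors and the Schlafen genes. Other splits of the 6 libraries called 0 genes each by limma, with 356 to 745 genes at an unadjusted p under 0.05 against 6967 in the real split, but up to 9 lists by camera. Each other split mixes treated and vehicle libraries on both sides. A treatment difference then enters the residual of limma, so few gene calls were likely there. Among random lists matched on peak-covered length, the mean of the PRC2-bound factors and of the non-neuroendocrine list stood at percentile 100, the Schlafen genes at 99.99, MHC class II at 99.93, blood markers at 97.86 and chemokines at 92.21. Of the lists not called, HOX genes stood at 100, clustered protocadherins at 0.01, PRC2 subunits at 0.43 and housekeeping genes at 2.74. Random lists held genes drawn singly, whereas HOX, protocadherin and Schlafen genes are neighbours with partly overlapping windows. The percentiles of these lists may therefore look more extreme than they are.

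**Figure D5:**
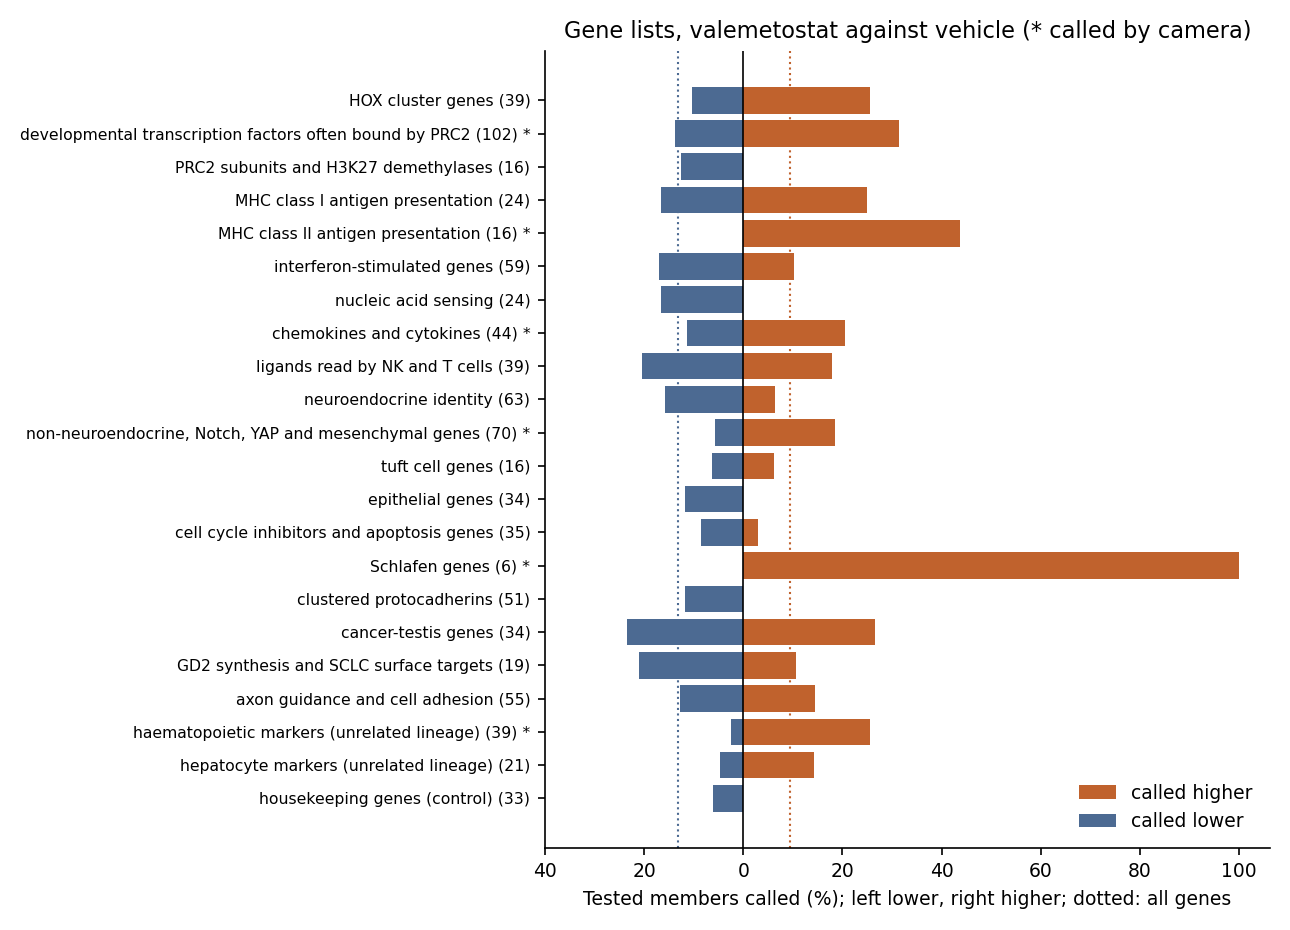
Percent of tested members (x axis) called lower (left) and higher (right) with valemetostat for each of the 22 gene lists, with the number tested in brackets, an asterisk where camera called the list, and dotted lines at the share over all genes (13.2% lower, 9.42% higher). The 6 Schlafen genes were all called higher.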

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

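The tests named here were chosen after the results were seen. Peaks on 4 unplaced or unlocalised sequences, left out of the comparisons, were more numerous in each valemetostat library than in each vehicle library. The means were 14 against 9.33 on an unlocalised sequence of chromosome 14, 15 against 7 on one of chromosome 15, 68.3 against 41.7 on one of chromosome 16 and 20 against 6.33 on one of chromosome 1 (n = 3 per group, no test). Of the 15 such sequences with a mean of 10 or more peaks, 4 had all valemetostat libraries above all vehicle libraries and 1 had the opposite, and chance gives 5% each way. They hold segments much like other parts of the genome, so the origin of their reads is uncertain.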

How the results depend on the processing

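The whole-gene window, one fixed width per region and centring on the median gene were chosen after seeing the data, and the cause of each difference below was not tested. At −log10 q of 10 or more, the difference in peaks was −6217, the difference in the share near gene ends was 0.618 percentage points (−0.846 at the authors' threshold, exact permutation p = 0.2) and gained regions numbered 4093. Calling at −log10 q of 5 against absence at the authors' threshold gave 5199 gained and 2580 lost regions, and 2 or more of 3 libraries gave 16420 and 9786. Gained against lost regions had an odds ratio near gene ends of 1.06 within 500 bp. Windows of 2 kb called 1295 genes (706 higher, 589 lower) and turned PHF19 (0.30), MUC4 (0.00688), BID (0.0275) and CEACAM5 (−0.00684). Windows of 50 kb called 11366 (3317 and 8049) and turned NEUROD2 (−0.0105). A −log10 q of 5 or more left 1546 genes lower, whole genes with 10 kb flanks gave 6675 calls (4440 lower) and centring left 1010 lower. With each region at one fixed width, 2064 genes were called (1004 higher, 1060 lower), and RTP4 (−0.0540), DAPK1 (−0.0522), ASGR1 (−0.0621) and TAP1 (−0.0449) turned. Camera with an estimated correlation called 2 lists. Leaving out 1 library at a time gave 9896 to 12065 gained and 5159 to 6458 lost regions. With a library fewer the rule for both kinds is looser, so a rise from 9016 and 4040 was built in. These 2 ranges therefore do not show how far the counts rest on a library. Leaving out 1 library also gave 2591 to 2928 genes called (1196 to 1419 higher, 1172 to 1659 lower). The covered-length difference was then −2.46 to 2.23 Mb, and the gained-against-lost odds ratio 0.874 to 1.07. The odds ratio was above 1 without vehicle replicate 1, 2 or 3. The balance of higher and lower genes turned without vehicle replicate 2 or 3, in 2 kb windows and with centring. Without vehicle replicate 1, which stood apart, 1404 genes were higher and 1480 lower and the covered-length difference was 2.23 Mb, and without valemetostat replicate 3 it was 0.0333 Mb. Lost regions numbered 6458 without vehicle replicate 3, under the looser rule. Genes called numbered 2616 without vehicle replicate 2, 2591 without vehicle replicate 3 and 2668 without valemetostat replicate 2, of which 1221, 1172 and 1463 were lower. The remaining ranges were 5129 to 9042 more peaks with valemetostat, −55.3 to −20.3 bp in median width, −1.32 to −0.472 percentage points near gene ends, 0.0912 to 0.111 in list agreement and 5 to 7 lists called. Against regions called in all libraries, the odds ratio was 0.202 to 0.215 for gained and 0.197 to 0.232 for lost regions. Of 67 named genes called higher, 36 kept the call in all 19 alternatives, and of 41 called lower, 5 did. Without vehicle replicate 1, 62 and 21 kept it. Chemokines and cytokines lost their call without valemetostat replicate 1 (adjusted p = 0.0522). Lists not called at first passed in some alternatives. Housekeeping genes, a control, were called without scaling (adjusted p = 0.0463), in 50 kb windows (0.0370), without vehicle replicate 1 (0.0184) and at one width (0.0314). Cancer-testis genes passed in 50 kb windows (0.00697), with whole genes (0.0450) and at one width (0.0394), clustered protocadherins in 50 kb windows (0.0297) and PRC2 subunits with whole genes (0.0463). Deviations of same-numbered libraries correlated at 0.0340, −0.00319 and 0.0242, too weakly to show whether replicate numbers pair the libraries. Vehicle replicates 1 and 3 correlated best with the valemetostat library of the same number, and vehicle replicate 2 with valemetostat replicate 3 (0.0283). With the replicate block, 3387 genes were called (1592 higher, 1795 lower) and 6 lists. Between same-numbered libraries, regions called only with valemetostat exceeded those called only in vehicle by 6167 per pair on average. The group differences in peaks and widths then had p = 0.25 by exact permutation, the smallest possible. The planned motif tests were not run, for want of a genome sequence. Depth is known only as a relative index, so absence of a call does not show closed chromatin.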

Other observations

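All tests of explanations below were chosen after the results were seen. None of the remaining lists was called by camera. Cancer-testis genes were higher in 9 and lower in 8 of 34 tested members (10 and 8 adjusted over the list alone; camera adjusted p = 0.135). GAGE2A (log2 change 1.93) and GAGE1 (1.69), near-identical X-linked copies and thus uncertain, rose with DPPA4 (1.68) and DPPA2 (0.90), germline chromatin genes that are neighbours on chromosome 3. Clustered protocadherins, neuronal cell-surface identity genes, fell in 6 of 51 members (6 adjusted over the list alone; camera adjusted p = 0.427), among them PCDHB16 (log2 change −0.98), PCDHB10 (−0.97), PCDHB9 (−0.84) and PCDHB8 (−0.76), whose windows overlap. Axon guidance and adhesion genes were higher in 8 and lower in 7 of 55 (9 and 8 adjusted over the list alone; adjusted p = 0.176). PLXNA4, a semaphorin receptor (776 ± 142 bp), and UNC5C, a netrin receptor (591 ± 388 bp), were at 0 bp in vehicle, EFNB2 rose (log2 change 0.78) and CDH9 fell (−0.78). Of SCLC surface targets, 2 rose and 4 fell of 19 (the same adjusted over the list alone; adjusted p = 0.754). NCAM1, a neuroendocrine adhesion molecule, fell from 3608 ± 8.98 to 2433 ± 81.7 bp (log2 change −0.49, adjusted p = 0.00101), with CDH6 at −0.32, CDH17 at 0.48 and CEACAM5 at 0.39 (−0.00684 in windows of 2 kb).

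Nucleic acid sensing genes fell in 4 of 24 and rose in 0 (the same adjusted over the list alone; camera adjusted p = 0.906), namely TBK1 (log2 change −0.49), ZNFX1 (−0.44), DHX58 (−0.40) and ZBP1 (−0.40). Epithelial genes fell in 4 of 34 (0 adjusted over the list alone; adjusted p = 0.169), with MUC4 (−0.35, but 0.00688 in windows of 2 kb), KRT7 (−0.30), ESRP1 (−0.29) and KRT17 (−0.27). Cell cycle inhibitors and apoptosis genes rose in 1 and fell in 3 of 35 (0 and 1 adjusted over the list alone; adjusted p = 0.423), with DAPK1 at 0.63 (−0.0522 with each region at one fixed width), GSDME at −0.89 and BID at −0.33 (0.0275 in windows of 2 kb). Tuft cell genes rose in 1 and fell in 1 of 16 (the same adjusted over the list alone; adjusted p = 0.176), with CHAT at 0.49 and AVIL at −0.38. Hepatocyte markers, an unrelated lineage, rose in 3 and fell in 1 of 21 (the same adjusted over the list alone; adjusted p = 0.754). SERPINA1 (2264 ± 696 bp) and TTR (912 ± 191 bp), secreted liver proteins, were at 0 bp in vehicle, ASGR1 was at 0.32 (−0.0621 with each region at one fixed width) and UGT2B7 at −0.86. Housekeeping genes fell in 2 of 33, PPIA (−0.42) and PSMD2 (−0.26), and rose in 0 (0 and 1 adjusted over the list alone; adjusted p = 0.0777). Camera, which is relative to all genes, gave the direction higher to 10 lists with a median below 0. The medians were −0.07 for HOX genes, −0.14 for MHC class I, −0.14 for NK and T cell ligands, −0.02 for blood markers, −0.15 for hepatocyte markers, −0.03 for cancer-testis, −0.05 for axon guidance and −0.00359 for tuft cell genes, all with means above 0. For interferon-stimulated genes (median −0.08, mean −0.05) and SCLC surface targets (median −0.02, mean −0.02) the mean was below 0 as well.

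The 9016 gained and 4040 lost regions stood against a highest value of 517 in the other splits, and the 4174 genes called against 0. In each of these, 1 of the 10 splits, the real one, gave as large a result. The 0 genes called are a weak comparison, because a treatment difference enters the residual of every other split and lowers its calls. The 6 lists called stood against up to 9 in another split, so 2 of the 10 splits called as many. That split set vehicle replicate 1 and valemetostat replicates 1 and 2, the 3 libraries with the most covered sequence, against the rest, and 5 of its 9 lists were among the 6. Vehicle replicate 1 with valemetostat replicates 1 and 3 gave 4 lists, and with valemetostat replicates 2 and 3 it gave 5. Vehicle replicates 1 and 2 with valemetostat replicate 3 gave 5. In each of these, 4 lists were among the 6. The remaining other splits called 0 or 1 list. Every other split parts the treated libraries 2 to 1, so a remaining treatment effect and another structure of the samples were not separated. With 10 splits no share can be under 0.05.

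Gained regions were close together along chromosomes. Weak calls are argued against as the whole cause, because the 1892 gained regions at −log10 q of 10 or more in all 3 lists made 123 adjacent pairs, against at most 40 in 1000 shuffles. A copy number gain of up to 2-fold in the treated cells cannot be told apart. Between 21.1% and 24.0% of gained peaks in the densest windows had a fold above 2 times the 99th percentile of the weakest peaks (−log10 q under 2) of the same list, which leaves the other peaks open. Chromosome 10 held 5.06 to 5.11% of peaks in vehicle and 5.48 to 5.57% in valemetostat lists. Chromosomes 19 (3.59 to 3.65% against 3.85 to 3.92%) and 20 (3.18 to 3.26% against 3.46 to 3.62%) rose too. Chromosomes 3 (6.60 to 6.63% against 6.15 to 6.18%) and 22 (2.16% against 1.92 to 1.96%) fell. Larger amplifications, GC content and a spread of open chromatin from loss of H3K27 methylation, which may be a biological explanation, were not tested.

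More regions were gained than lost at the authors' threshold. Greater depth of the treated libraries, as read from the depth index, is argued against as the whole cause. The 2 valemetostat libraries below every vehicle library in this index, set against each pair of vehicle libraries, gave 1.36 to 1.62 times as many regions called only with valemetostat as only in vehicle. Weak peaks near the threshold cannot be told apart, because the ratio of gained to lost regions was 0.814 at −log10 q of 10 or more, against 2.23 at the authors' threshold, but 1.71 for regions at 10 or more in one group and absent from the other at the authors' threshold. It was 1.58 at 5 or more and 1.57 with lists of equal length. Median −log10 q was 26.1, 24.3 and 21.4 in vehicle and 16.4, 14.7 and 14.8 in valemetostat replicates 1, 2 and 3. Median fold was 7.78, 8.62 and 7.91 against 6.55, 6.76 and 6.75. Valemetostat replicate 1 was below vehicle replicates 2 and 3 in both, although its depth index was higher. The cause of these lower values was not tested. Lower depth, which itself lowers −log10 q, and an effect of treatment may contribute and stay open.

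Peaks were narrower with valemetostat at the authors' threshold (−11.3 bp at −log10 q of 10 or more) and many genes were lower by a small amount. With each region at one width, the median log2 change of all 2432 genes called lower moved from −0.37 (median SE 0.0833) to −0.24 (median SE 0.0590), against −0.06 over all genes. That gap is smaller than the median absolute deviation of these genes (0.181), which is their spread and not the error of the median. The genes were also chosen as lower in the same data, so a median below that of all genes was likely. Peak width and a real loss therefore cannot be told apart as the cause. Of these genes, 720 passed at one width, and for the other 1712 the call ended as the median change became smaller (−0.36 to −0.19) while the median SE went from 0.0845 to 0.0699. Lower depth cannot be told apart either, since only 1 valemetostat library, replicate 1, was deeper than a vehicle library and still narrower than it, and an effect of treatment on peak shape may also contribute and was not tested.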
